A study of Mus musculus with 12 samples.

How the data were processed

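RNA of 12 cultures of NIH-3T3, an immortalised line of mouse embryonic fibroblasts, was measured on Illumina mouse bead arrays, with 1 array per culture. Per the labels, the cells were unmodified (WT), a stable clone with a construct named as a short hairpin against Snhg3, the host transcript of the H/ACA box small nucleolar RNA U17 (U17_KD), or a stable clone with a construct whose name joins beta-globin and U17b (U17_OE). Each group has 4 arrays, named biological replicates in the labels, and all cells were kept in medium with lipoprotein-deficient serum for 24 hours, which withdraws external cholesterol. Each manipulated group is 1 clone, so a change caused by the level of U17 and a change particular to that clone cannot be told apart by any comparison here. The groups were read from the sample titles.

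Per the labels, cDNA was primed with oligo-dT and labelled with biotin, and the submitters' processing notes name GenomeStudio 2010. The authors deposited 2 tables. The main input was the authors' normalized table of probe intensity values on a linear scale, with background subtracted, so that 37.7% of the values of WT replicate 1 lie below 0. Its quartiles are nearly equal on all 12 arrays while its maxima differ. The method of normalization between arrays is not given in the sources used here. The other deposited table holds the intensity before normalization and a detection p-value per probe, per the file headers. Of that table, the signal and detection p-value of the WT arrays were used, and the other 40 of its 48 columns were not. The columns of the 8 other arrays were left out because the names of those arrays occur in no label. Signals of the WT arrays in the 2 tables had a Spearman rho of 1.00 over 45281 probes.

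The plan written before the data were examined was neqc on the unnormalized signals of all arrays with their own detection p-values. With only the WT arrays of that table in use, the normalized table took its place and was not normalized again between arrays. Background mean (0.492) and SD (15.8) were estimated from the detection p-values of the WT arrays and used in the normexp correction of all 12 arrays, followed by log2 after adding an offset of 16. This background setting was chosen after a preliminary fit, with normexp fitted to each array's own values, and its leading genes and counts had been seen. It was preferred because it lies closest to the plan. It left the number of probes called almost unchanged but gave more probes changed at least 2-fold, so those counts depend on it, and both versions are given in the closing section.

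A probe was taken as detected where its value reached 30.5, the mean over the WT arrays of the lowest normalized value with a detection p-value under 0.05. On the WT arrays this level and the detection p-value disagreed for 0.155 to 1.51% of the probes. Whether the level holds equally for the clone arrays was not tested. Probes detected on at least 4 arrays were kept, 16706 of 45281. Probes were named through the platform annotation, in which 34885 probes have 1 gene symbol, 18 have several and 10378 are not listed. Of those with 1 symbol, 34807 matched a RefSeq gene of GRCm38.p6 by gene ID, with 0 symbols changed. No coordinates are given, since no genome build is named in the sources used here. The kept probes hold 14181 with a name, for 9108 genes, and 2525 without. For each gene the probe with the highest mean over the arrays was used, and other probes are mentioned where they differ in direction or call in a comparison for which the gene's value is given.

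Differences were tested with limma 3.58.1 in R 4.3.3, in 1 linear model with the 3 groups, 12 arrays and 9 residual degrees of freedom, with moderated variances that follow a mean-variance trend. P-values were adjusted by Benjamini-Hochberg over the kept probes, separately in each comparison, with a threshold of 0.05, and all tests are two-sided. A probe below the detection level on all 4 arrays of a group has only a bound there. The fold is then written as at least N-fold, from the mean of the brighter group over the higher, per array, of the dim probe's own value and the lowest value among detected probes. The 21 gene lists, fixed before the data were examined, cover cholesterol synthesis, SREBP regulation and lipid uptake, cholesterol trafficking and efflux, mitochondrial dynamics and ER contact, sterol import and steroidogenesis, snoRNA host genes other than Snhg3, snoRNP and rRNA processing, p53 targets, the cell cycle, the interferon response, the integrated stress and unfolded protein response, hypoxia, oxidative stress and NRF2, extracellular matrix, TGF-beta and contractile genes, ribosomal proteins, and markers of fibroblasts, adipocytes, muscle with bone and cartilage, macrophages, and epithelial with endothelial cells. Each list was tested against the other genes with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. The self-contained test fry, which asks whether the genes of a list move one way and does not compare them with other genes, was also run.

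The groups, the 3 comparisons, the limma model, the number of arrays in the filter, the gene lists, the alternatives not named as added, and the rule for the genes named here were fixed before the data were examined. The detection level was set after the files were seen, where the plan used each array's own detection p-value for the filter and the rule. The rule takes, in each comparison, the 8 largest rises and the 8 largest falls among genes called at the threshold, detected on at least 3 arrays of both groups and without overlap between the groups' values, leaving out predicted and unnamed genes. It adds the 3 genes per direction with the highest bound among those detected on 4 arrays of one group and 0 of the other, up to 3 called members of each list, members of the cholesterol and sterol lists given as not passing, and the probes of the design's own genes. It also adds the 8 genes per direction changed in opposite directions in the clones and the 5 per direction changed the same way.

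The limma step was tested on simulated data with the real probe means and residual SDs over 16706 probes, with 200 probes changed per clone in 10 runs. In U17_KD minus WT it recovered 44.4% of the probes changed by 0.5 on the log2 scale, 91.4% of those changed by 1 and 99.5% of those changed by 2, and 4.24% of all calls were false. In U17_OE minus WT the shares were 46.6, 93.8 and 99.7%, with 4.44% false calls, and in U17_KD minus U17_OE they were 52.1, 94.9 and 99.8%, with 5.32% false calls. The simulation drew independent normal noise on values already corrected and filtered, with 1 SD per probe for all groups. It did not test the background correction, the detection level, correlation between probes or unequal spread of the groups. With 200 probes changed per clone, against 37.3 and 11.5% of probes called in U17_KD and U17_OE minus WT, these shares need not hold here. The precision of each value is limited by the number of arrays. Alternatives changed the background correction, the offset, the normalization, the filter, the variance model, the weights of the arrays, the arrays in the fit, a block on the replicate number, the thresholds, the choice of probe and the correlation in camera, and left out each array in turn.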

Results

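Expression was measured in WT NIH-3T3 fibroblasts, in a clone labelled as a U17 knockdown and in a clone labelled as overexpressing U17, with 4 arrays per group, to find messenger RNAs that follow the level of this small nucleolar RNA. Between 15820 and 15832 probes were detected per array. This near equality follows from 1 detection level on values already normalized between arrays, and is no measure of array quality. By their own detection p-values, the WT arrays had 15140 to 16182 probes under 0.05. The correlation between arrays over the kept probes was 0.980 to 0.995 within a group (18 pairs) and 0.966 to 0.989 between groups (48 pairs). The principal component with the largest share, 51.6% of the variance, set the U17_KD arrays apart from the others. U17_OE replicate 3 lay apart from its group: its SD of differences from its group mates was 0.393 on the log2 scale, against 0.182 to 0.273 for the other arrays.

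No probe named Snhg3, Snora73a or Snora73b was found, so the level of U17 and of its host transcript in the clones was not checked by these arrays. Rcc1, the gene next to Snhg3, which encodes the exchange factor of the GTPase Ran, had a mean log2 intensity of 9.54 ± 0.19 (SD, n = 4) in WT, 8.61 ± 0.04 in U17_KD and 9.31 ± 0.11 in U17_OE. It was lower in U17_KD than in WT by limma (log2 fold change -0.92 ± 0.10 SE, adjusted p = 8.62e-07). In U17_OE its difference from WT was -0.22 ± 0.10 (adjusted p = 0.183), and without WT replicate 2 it was -0.32 (adjusted p = 0.0443). Mgarp, which encodes a mitochondrial protein induced by hypoxia and also called HUMMR, had means of 7.60 ± 0.25 in WT, 9.22 ± 0.11 in U17_KD and 5.46 ± 0.35 in U17_OE. It rose by 1.62 ± 0.16 in U17_KD (adjusted p = 2.40e-07) and fell by 2.14 ± 0.16 in U17_OE (adjusted p = 5.01e-08), where 1 of 4 arrays detected it, so that the size of this fall rests mostly on values below the detection level. Mgarp is known as a U17 target from the study of these cells, so its direction here is not independent evidence. A probe of the embryonic globin gene Hbb-bh1 was detected on 4 of 4 arrays of WT and of U17_OE and on 0 of 4 of U17_KD, and was at least 10.2-fold lower in U17_KD than in WT (adjusted p = 1.19e-13) and lower in U17_OE (-1.14 ± 0.14, adjusted p = 1.56e-05). A second probe of Hbb-bh1 was detected on 0 of 4 arrays of each group, as were all probes of Hba-a1, Hbb-bt, Hbb-y and Hbb-b2. The kept probe of Hbb-bs with the highest mean, detected on 2, 1 and 1 arrays of WT, U17_KD and U17_OE, had -0.22 ± 0.17 against WT in both clones (adjusted p = 0.356 in U17_KD and 0.498 in U17_OE). Its other kept probe, detected on 3, 1 and 2 arrays, had -0.51 ± 0.21 in U17_KD (adjusted p = 0.0596) and -0.43 ± 0.21 in U17_OE (adjusted p = 0.207).

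**Figure D1:**
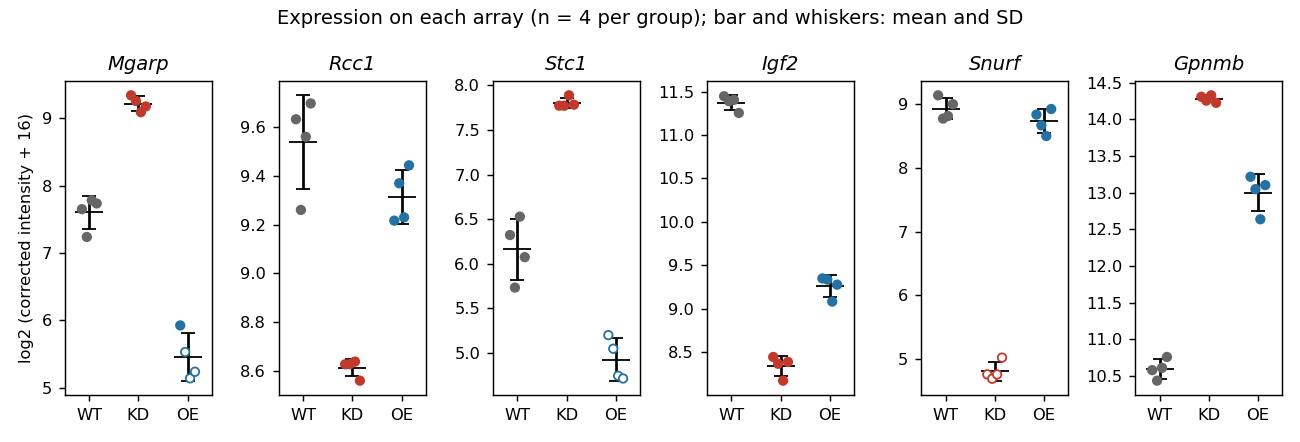
Each panel plots 1 gene, with the log2 of the background-corrected intensity plus 16 on the vertical axis and the groups WT, U17_KD (KD) and U17_OE (OE) on the horizontal axis; points are arrays (n = 4 per group, open where not detected), and the bar with whiskers is the mean and SD. The vertical axes differ between panels. Mgarp lies at 7.60 in WT, 9.22 in U17_KD and 5.46 in U17_OE, while Gpnmb is higher and Igf2 lower in both clones than in WT.

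The comparison of U17_KD with WT asks which transcripts changed in the knockdown clone. Among genes detected in both groups, the largest rises were those of Ly6c1, a surface antigen of the Ly6 family (log2 fold change 4.09 ± 0.10 SE, adjusted p = 2.06e-15), Olfm1, a secreted olfactomedin (4.03 ± 0.14), Srpx2, a secreted sushi-repeat protein (3.98 ± 0.14), and Gpnmb, a glycoprotein of lysosomes and melanosomes (3.68 ± 0.10). They were followed by the pentraxin Ptx3 (3.46 ± 0.17), the water channel Aqp5 (3.18 ± 0.11), the glutamate transporter Slc1a3 (3.08 ± 0.10) and the zinc finger gene Tshz3 (2.91 ± 0.12). The largest falls were those of Renbp, which encodes a renin-binding epimerase (-4.19 ± 0.12, adjusted p = 1.08e-14), the serine protease Klk8 (-3.12 ± 0.15), the imprinted growth factor gene Igf2 (-3.04 ± 0.09) and the copine Cpne8 (-2.48 ± 0.11). Dusp5, a phosphatase of ERK (-2.44 ± 0.12), the lectin-like receptor Klra4 (-2.41 ± 0.17), the autophagy gene Atg9b (-2.30 ± 0.14) and Cdsn, which encodes corneodesmosin (-2.29 ± 0.12), completed the largest falls. Among genes detected in U17_KD on all arrays and in WT on none, Lmcd1 was at least 11.1-fold higher, Brinp3 at least 9.06-fold and the aldo-keto reductase Akr1c12 at least 6.35-fold. In the other direction Snurf, an imprinted gene that shares its transcript with Snrpn, was at least 10.5-fold lower and the matrix-associated gene Smoc1 at least 10.2-fold lower.

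In this comparison limma called 6237 of 16706 probes, 3079 higher and 3158 lower, of which 842 changed at least 2-fold (521 higher, 321 lower). By gene, 3685 of 9108 were called and 499 changed at least 2-fold. The values of the groups did not overlap for 40.6% of the probes, against 2.86% by chance. The WT cells and the clone were compared across 1 clone, so the replicate spread does not include the spread between clones.

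Genes of ribosome production fell in the knockdown clone. Of 34 measured members of the snoRNP and rRNA processing list, 24 were lower, 0 were higher and 10 did not pass (25 lower when adjusted over the list alone), with a camera adjusted p of 7.86e-08 and an adjusted p of 0.00166 with an estimated correlation. Tbl3, a component of the small subunit processome, fell by 1.18 (adjusted p = 1.72e-07), Ncl, which encodes nucleolin, by 0.99, and Rrp12, which acts in ribosomal subunit maturation, by 0.86. All 3 measured snoRNA host genes other than Snhg3 were also lower (3 adjusted over the list alone), namely Snhg5 (-0.75), Snhg12 (-0.45) and Snhg10 (-0.30). The call of that list (camera adjusted p = 0.0436) was lost with an estimated correlation (adjusted p = 0.138), without U17_KD replicate 3 (0.0643), with no filter on detection (0.148) and with a stricter one (0.0594). Over the 21 alternatives run for lists its adjusted p ranged from 0.0342 to 0.148. Ribosomal protein genes did not shift as a list: 3 were higher and 9 lower of 49 (3 and 8 adjusted over the list alone), with a camera adjusted p of 0.948. Rps15a (-0.52) and Rpl4 (-0.40) fell, and Rpl31 rose by 0.27.

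Cholesterol synthesis genes were mostly higher in the knockdown clone, with 10 higher and 1 lower of 14 measured (11 and 1 adjusted over the list alone). Mvk, which encodes mevalonate kinase, rose by 1.38 (adjusted p = 1.16e-07) and Dhcr7, the last reductase of the pathway, by 0.85, while Tm7sf2, a sterol reductase, fell by 0.91. Msmo1 (0.18), Sc5d (0.26) and Ebp (0.11) did not pass. The list's camera adjusted p was 0.00212, and its adjusted p with an estimated correlation was 0.126. Of 5 measured sterol import and steroidogenesis genes 3 were higher and 0 lower (4 and 0 adjusted over the list alone; camera adjusted p = 0.026, and adjusted p = 0.126 with an estimated correlation). They were Hsd11b1, which activates glucocorticoids (at least 2.53-fold higher, detected on 0 WT arrays), Tspo, the translocator protein of the outer mitochondrial membrane (0.44), and Hsd3b7, an enzyme of bile acid synthesis (0.32). Cholesterol trafficking and efflux genes went both ways, 5 higher and 5 lower of 19 (5 and 5 adjusted over the list alone, camera adjusted p = 0.996). The START domain gene Stard5 rose by 1.29, while the lipoprotein receptor Vldlr was at least 3.62-fold lower and Apoe at least 1.19-fold lower, both detected on 0 U17_KD arrays. The transporters of lysosomal cholesterol Npc1 (0.04) and Npc2 (0.01) did not pass. Of the SREBP regulation and uptake list, 5 of 15 were higher and 1 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.211), among them Insig2 (0.83), which restrains SREBP processing, and Mylip, which restrains LDL uptake (at least 1.19-fold higher, detected on 0 WT arrays). Without the filter on detection that list was called (adjusted p = 0.0456).

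Extracellular matrix genes rose in the knockdown clone, 23 of 36 measured, with 7 lower (24 and 8 adjusted over the list alone). Ogn, a small leucine-rich proteoglycan, rose by 2.76 and Lox, which crosslinks collagen, by 1.85, whereas the related proteoglycan Lum was at least 2.87-fold lower. Fbln2, of the same list, had -1.06, but 1 of its 2 other probes was called in the opposite direction (1.12). The camera adjusted p was 2.19e-05, and the adjusted p with an estimated correlation was 0.0686. Interferon response genes were higher for 8 of 18 and lower for 2 (9 and 2 adjusted over the list alone), with rises of the guanylate-binding protein Gbp2 (2.24) and of Isg15 (1.27), and with Gbp3 at least 2.14-fold higher. Their camera adjusted p was 0.00963 (adjusted p = 0.0686 with an estimated correlation). Cell cycle genes were lower for 12 of 31 and higher for 2 (14 and 2 adjusted over the list alone), with Rrm2, a subunit of ribonucleotide reductase, at -1.12 and Ccnd1, cyclin D1, at -0.74. Kif23 had 1.08, but its 3 other probes lay between -0.32 and -0.20 and none was called. The camera adjusted p was 0.022 (adjusted p = 0.0686 with an estimated correlation). Hypoxia genes were higher for 10 of 21 and lower for 1 (10 and 1 adjusted over the list alone). The hexokinase Hk1 rose by 1.08, P4ha2, a collagen prolyl hydroxylase, by 0.95 and Adm, adrenomedullin, by 0.73. The camera adjusted p of 0.0325 was lost with an estimated correlation (adjusted p = 0.135) and without U17_KD replicate 3 (0.0643), and ranged from 0.0243 to 0.135 over the 21 alternatives run for lists.

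The other lists were not called in U17_KD minus WT. The integrated stress and unfolded protein response had 10 higher and 12 lower of 31 (camera adjusted p = 0.453), with falls of the cystine transporter Slc7a11 (-2.26), detected on 1 U17_KD array, and of the serine enzyme Shmt2 (-1.34). The 2 other probes of Slc7a11 were not called. Oxidative stress genes had 7 higher and 6 lower of 24 (0.948), with Sod3 at least 3.88-fold higher and Gstm1 at 1.63, TGF-beta and contractile genes 9 and 8 of 24 (0.948), with Actg2 at least 3.02-fold lower and Ankrd1 at -1.42, and p53 targets 6 and 4 of 20 (0.414), with Fas at 2.00. Mitochondrial dynamics and ER contact genes had 2 and 2 of 18 (0.906), with Mgarp at 1.62 and Rhot2 at -0.99. Fibroblast markers were higher for 8 and lower for 2 of 15 (0.0662), and were called with no filter on detection (0.0401), without U17_OE replicate 2 (0.0487) and without U17_OE replicate 3 (0.0457). Of the markers of other cell types, adipocyte genes had 2 and 2 of 9 (0.521), muscle, bone and cartilage genes 0 and 1 of 6 (0.521), macrophage genes 0 and 0 of 5 (0.577) and epithelial and endothelial genes 1 and 2 of 7 (0.948). Adjusted over the list alone, the counts were the same for each list in this paragraph. Median and mean differed in sign for the trafficking, oxidative stress, TGF-beta, epithelial and ribosomal protein lists.

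The comparison of U17_OE with WT asks the same of the overexpression clone. Among genes detected in both groups, Gpnmb (log2 fold change 2.40 ± 0.10 SE, adjusted p = 3.30e-11) and Srpx2 (2.25 ± 0.14) rose most, followed by the serine protease inhibitor Serpina3n (1.91 ± 0.10), the cilia gene Cfap161 (1.90 ± 0.11), the aldehyde dehydrogenase Aldh3a1 (1.75 ± 0.14), Ly6c1 (1.62 ± 0.10), Olfm1 (1.61 ± 0.14) and the amino acid transporter Slc6a15 (1.59 ± 0.19). A second kept probe of Slc6a15 showed no such rise (-0.19), and 1 of the 3 other probes of Gpnmb was not called. The largest falls were those of Tmem181c-ps (-2.31 ± 0.12, adjusted p = 5.16e-10), Igf2 (-2.12 ± 0.09), the adhesion gene Flrt3 (-1.88 ± 0.22) and the imprinted gene Ndn, which encodes necdin (-1.82 ± 0.10). Klra4 (-1.60 ± 0.17), the chemokine Cxcl12 (-1.57 ± 0.13), Mfap3l (-1.46 ± 0.13) and the G protein regulator Rgs16 (-1.40 ± 0.14) followed. Tmem176b was at least 3.79-fold higher, Zfp704 at least 2.60-fold and the extracellular superoxide dismutase Sod3 at least 2.53-fold, each detected on 0 WT arrays. The lysophosphatidic acid receptor Lpar4 was at least 4.64-fold lower, Epop at least 3.96-fold and Tmem181a at least 3.51-fold, each detected on 0 U17_OE arrays.

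In this comparison limma called 1925 probes, 1001 higher and 924 lower, and 152 changed at least 2-fold (88 higher, 64 lower). By gene, 1170 of 9108 were called and 95 changed at least 2-fold (45 higher, 50 lower), so the lead of rises among probes did not hold by gene. The values of the groups did not overlap for 14.2% of the probes, against 2.86% by chance. The count of calls depended on single arrays: it was 2981 without U17_OE replicate 3 and 1261 without U17_OE replicate 4.

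Hypoxia genes fell in the overexpression clone, 12 of 21 with 0 higher (15 lower adjusted over the list alone, camera adjusted p = 3.80e-08, and adjusted p = 0.0104 with an estimated correlation). Egln3, an oxygen-sensing prolyl hydroxylase, fell by 1.26 (adjusted p = 4.23e-05), Ak4, a mitochondrial adenylate kinase, by 0.71 and Egln1 by 0.70. Cholesterol synthesis genes rose, 7 of 14 with 0 lower (8 and 0 adjusted over the list alone, camera adjusted p = 8.61e-07, and adjusted p = 0.0428 with an estimated correlation). Mvk rose by 1.13, Dhcr7 by 0.66 and Lss, lanosterol synthase, by 0.57 (0.30 and not called at its other probe), with Sqle at 0.20 and Cyp51 at 0.15 not passing. Stress response genes fell, 12 of 31 with 1 higher (12 and 1 adjusted over the list alone, camera adjusted p = 0.00424, and adjusted p = 0.0514 with an estimated correlation). Among them were Slc7a11 (-1.01, with 2 other probes not called), Vldlr (-0.77) and the pseudokinase Trib3 (-0.74).

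Of the other lists, 3 were also called. Cell cycle genes were lower for 6 of 31 and higher for 1 (8 and 2 adjusted over the list alone, camera adjusted p = 0.0265, and adjusted p = 0.0514 with an estimated correlation), with Rrm2 at -0.79 and Ccne1, cyclin E1, at -0.53. The snoRNP and rRNA processing list had 6 lower and 0 higher of 34 (8 and 0 adjusted over the list alone, camera adjusted p = 0.0281, and adjusted p = 0.0514 with an estimated correlation), with Wdr3 at -0.60 and Ncl at -0.40 (-0.30 and not called at its other probe). This call was lost without U17_OE replicate 3 (adjusted p = 0.0918) and with a stricter filter on detection (0.0565), and ranged from 0.0134 to 0.0918 over the 21 alternatives run for lists. Sterol import genes had 2 higher and 0 lower of 5 (2 and 0 adjusted over the list alone, camera adjusted p = 0.036, and adjusted p = 0.149 with an estimated correlation), Hsd3b7 at 0.45 and Tspo at 0.26, of whose 2 other probes 1 was not called. The list's call was lost without WT replicate 1 (0.0524), WT replicate 2 (0.0785), U17_OE replicate 1 (0.11) or U17_OE replicate 2 (0.0587). A stricter filter on detection also ended it (0.0565), and its adjusted p ranged from 0.0188 to 0.149 over the same alternatives.

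The other lists were not called in U17_OE minus WT. The numbers of higher and lower members with the camera adjusted p were 2 and 0 of 15 for SREBP regulation and uptake (0.179), 3 and 1 of 19 for cholesterol trafficking and efflux (0.94), with Lipa at 0.52 (0.10 and not called at its other probe), and 0 and 1 of 18 for mitochondrial dynamics (0.276), the 1 being Mgarp. They were 0 and 0 of 3 for snoRNA host genes (0.545), 2 and 1 of 20 for p53 targets (0.531), 2 and 0 of 18 for the interferon response (0.531) and 4 and 5 of 24 for oxidative stress (0.94). They were 8 and 5 of 36 for extracellular matrix (0.276), whose median was above 0 and mean below, 3 and 5 of 24 for TGF-beta genes (0.179) and 2 and 0 of 49 for ribosomal proteins (0.25). Fibroblast markers had 2 and 1 of 15 (0.141), adipocyte markers 2 and 0 of 9 (0.141), muscle, bone and cartilage markers 0 and 1 of 6 (0.276), macrophage markers 2 and 0 of 5 (0.141) and epithelial and endothelial markers 0 and 0 of 7 (0.608). Adjusted over the list alone, the counts were 4 and 0 for SREBP regulation, 2 and 2 for p53 targets, 6 and 5 for oxidative stress, 13 and 6 for extracellular matrix, 4 and 5 for TGF-beta genes, 1 and 1 for muscle, bone and cartilage and 7 and 1 for fibroblast markers, and the same for the other lists in this paragraph. Without the filter on detection the SREBP, TGF-beta and macrophage lists were called (adjusted p = 0.0474 each). The interferon median was below 0 and its mean above, and the trafficking median and mean were below 0 with a test direction above.

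**Figure D2:**
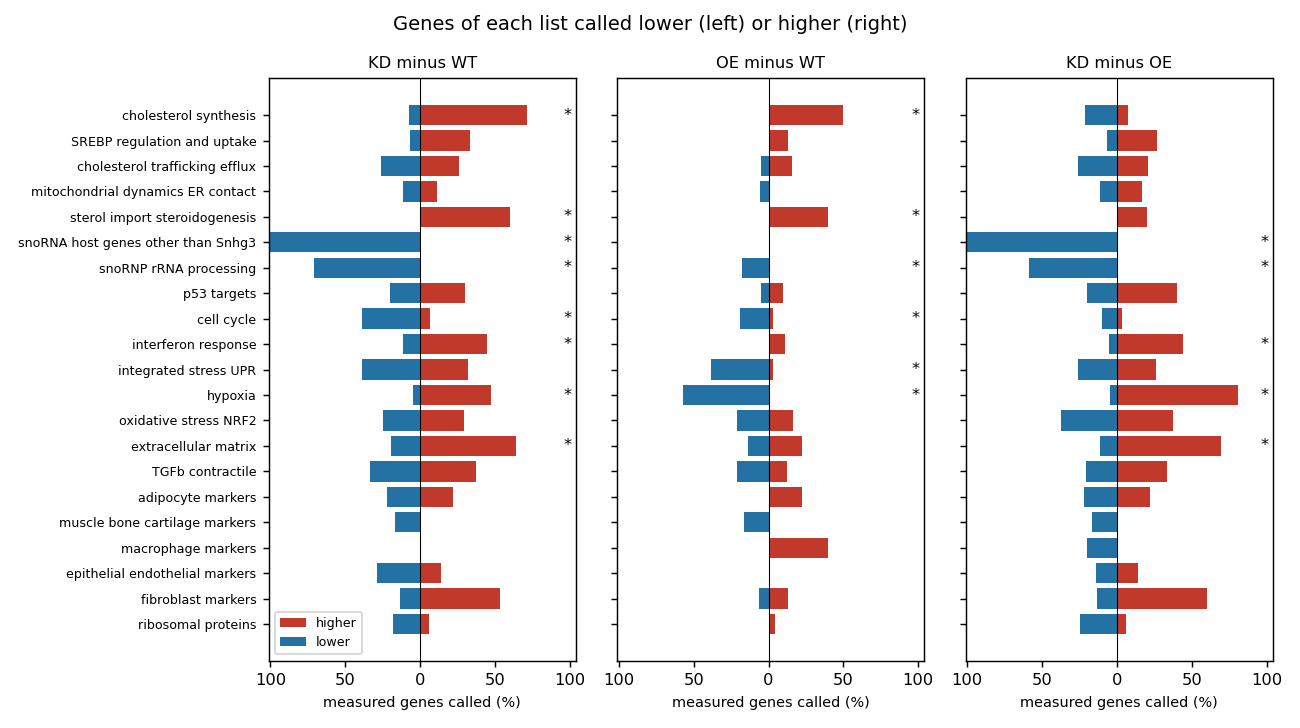
Bars give the percent of each list's measured genes called higher (red, to the right) or lower (blue, to the left) in each of the 3 comparisons, with KD for U17_KD and OE for U17_OE; a star marks a camera adjusted p under 0.05 at the preset correlation. The hypoxia list has 10 of 21 genes higher in U17_KD and 12 of 21 lower in U17_OE, each against WT.

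The direct comparison of the clones asks which transcripts separate the clone labelled as knockdown from the clone labelled as overexpression. Lmcd1 (log2 fold change 3.38 ± 0.13 SE, adjusted p = 1.01e-12), Tmem181c-ps (3.31 ± 0.12), Ptx3 (3.29 ± 0.17) and Ogn (3.16 ± 0.16) were highest in U17_KD relative to U17_OE, apart from genes below detection in a clone. The homeobox gene Rhox5 (2.88 ± 0.10), Tshz3 (2.73 ± 0.12), the matrix protease Adamts9 (2.48 ± 0.16) and Slc1a3 (2.48 ± 0.10) followed. Renbp (-4.50 ± 0.12, adjusted p = 8.71e-15), the teneurin Tenm4 (-2.89 ± 0.13), Dkk3, a secreted protein of the dickkopf family (-2.83 ± 0.15), and Fez1 (-2.57 ± 0.09) were lowest. Klk8 (-2.48 ± 0.15), Atg9b (-2.31 ± 0.14), the potassium channel Kcnn4 (-2.18 ± 0.12) and Cpne8 (-2.09 ± 0.11) were also lower. Brinp3 was at least 9.06-fold higher in U17_KD, Lpar4 at least 6.17-fold and the collagen receptor subunit Itga11 at least 5.31-fold, while Snurf was at least 9.11-fold lower, Smoc1 at least 7.07-fold and the smooth muscle actin gene Actg2 at least 6.36-fold.

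Between the clones limma called 5024 probes, 2477 higher and 2547 lower in U17_KD, with 587 changed at least 2-fold (341 higher, 246 lower). By gene, 3012 of 9108 were called and 348 changed at least 2-fold. The values did not overlap for 28.7% of the probes, against 2.86% by chance.

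Hypoxia genes were higher in U17_KD than in U17_OE for 17 of 21, with 1 lower (17 and 2 adjusted over the list alone, camera adjusted p = 3.39e-08, and adjusted p = 0.00508 with an estimated correlation). The largest differences were those of P4ha2 (1.29), Pdk1, a kinase that inhibits pyruvate dehydrogenase (1.27), and Egln3 (1.02). Extracellular matrix genes were higher for 25 of 36 and lower for 4 (27 and 5 adjusted over the list alone, camera adjusted p = 8.37e-08, and adjusted p = 0.0318 with an estimated correlation), with Ogn at 3.16, Lox at 1.70 and Col3a1 at 1.46. The snoRNP and rRNA processing genes were lower for 20 of 34 and higher for 0 (21 and 1 adjusted over the list alone, camera adjusted p = 6.38e-07, and adjusted p = 0.0035 with an estimated correlation), with Tbl3 at -1.24, Rrp9 at -0.88 and Pwp2 at -0.74 (-0.36 and not called at its other probe). The 3 snoRNA host genes were lower (3 adjusted over the list alone, camera adjusted p = 0.0116, and adjusted p = 0.102 with an estimated correlation). Interferon response genes were higher for 8 of 18 and lower for 1 (9 and 1 adjusted over the list alone, camera adjusted p = 0.0116, and adjusted p = 0.0535 with an estimated correlation), with Gbp2 at 2.34. Cholesterol synthesis genes did not separate the clones, with 1 higher and 3 lower of 14 (1 and 3 adjusted over the list alone, camera adjusted p = 0.851).

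The remaining lists were not called between the clones. The numbers of genes higher and lower in U17_KD with the camera adjusted p were 4 and 1 of 15 for SREBP regulation and uptake (0.833), 4 and 5 of 19 for cholesterol trafficking and efflux (0.894), 3 and 2 of 18 for mitochondrial dynamics (0.703) and 1 and 0 of 5 for sterol import (0.475). They were 8 and 4 of 20 for p53 targets (0.149), 1 and 3 of 31 for the cell cycle (0.475), 8 and 8 of 31 for the stress response (0.851), 9 and 9 of 24 for oxidative stress (0.833), 8 and 5 of 24 for TGF-beta genes (0.703) and 3 and 12 of 49 for ribosomal proteins (0.475). Fibroblast markers had 9 and 2 of 15 (0.196), adipocyte markers 2 and 2 of 9 (0.833), muscle, bone and cartilage markers 0 and 1 of 6 (0.894), macrophage markers 0 and 1 of 5 (0.833) and epithelial and endothelial markers 1 and 1 of 7 (0.894). Adjusted over the list alone, the counts were 4 and 6 for trafficking, 10 and 9 for oxidative stress, 10 and 6 for TGF-beta genes and 9 and 3 for fibroblast markers, and the same for the other lists in this paragraph. Median and mean differed in sign for the cholesterol synthesis, SREBP, trafficking, stress response, muscle and epithelial lists. Fry, which does not compare a list with other genes, called 17 lists in U17_KD minus WT, 14 in U17_OE minus WT and 13 between the clones.

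**Figure D3:**
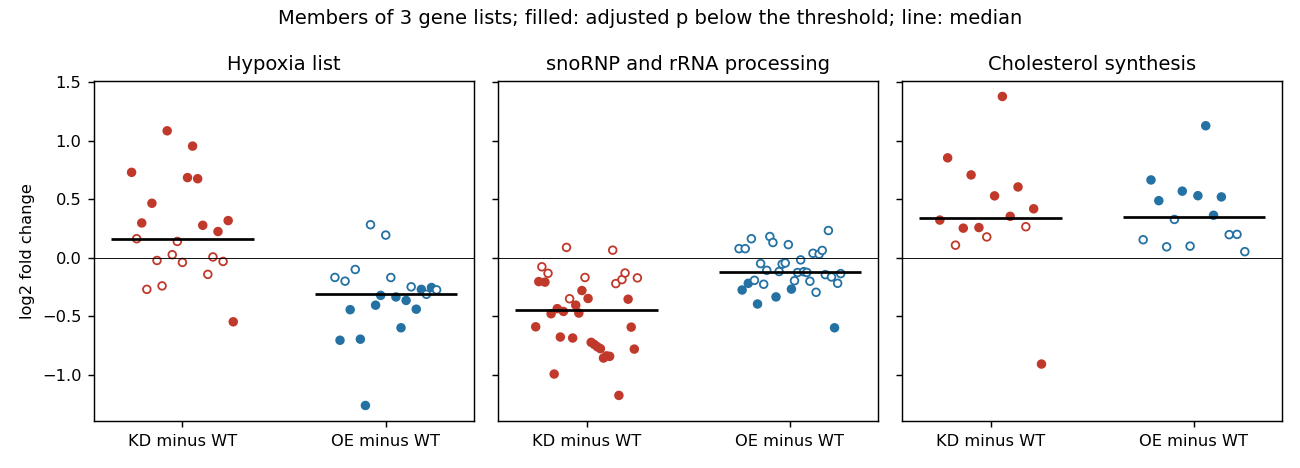
Points are the measured genes of 3 lists, with the log2 fold change against WT on the vertical axis and the clone (KD for U17_KD, OE for U17_OE) on the horizontal axis; filled points have an adjusted p under 0.05 and the line is the list's median. The hypoxia median is 0.16 in U17_KD and -0.31 in U17_OE, and the cholesterol synthesis median is 0.34 in both, with Tm7sf2 called lower in U17_KD.

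A messenger RNA that follows the level of U17 both below and above that of WT would change oppositely in the clones. This holds only if U17 changed as labelled, which was not measured. One that responds only to loss or only to gain would not be found this way. Genes called in both comparisons with WT were ranked by the smaller of their 2 fitted changes. Of them, 50 were higher in U17_KD and lower in U17_OE and 42 the reverse. With Mgarp, the 8 largest of the former were Stc1, which encodes the hormone stanniocalcin (1.64 in U17_KD and at least 1.54-fold lower in U17_OE), the proton channel Hvcn1 (1.20, and at least 1.79-fold lower), the collagen-degrading protease Ctsk (1.07 and -1.29), Tmem181c-ps (1.00 and -2.31), Rab29 (1.11 and -0.88), Tril (0.96 and -1.15, detected on 1 U17_OE array) and Cthrc1 (0.80, and at least 1.42-fold lower). Of the reverse kind were Actg2 (at least 3.02-fold lower in U17_KD and 1.07 in U17_OE), Slc6a15 (at least 1.40-fold lower and 1.59, with a second probe not called), Sdc3 (-1.29 and 0.78), the Wnt antagonist Sfrp1 (-0.89 and 0.89), Slc17a6 (-0.81 and 1.02), Mycl (at least 1.06-fold lower and 0.77), Gdap1l1 (-0.78 and 0.85) and Naprt (0.73 in U17_OE and lower in U17_KD, adjusted p = 0.00011). Stc1, Hvcn1 and Cthrc1 were not detected on any U17_OE array, and Actg2, Slc6a15 and Mycl on no U17_KD array.

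More genes changed the same way in both clones than oppositely, 414 higher and 365 lower in both. The shared rises with the largest smaller fitted change were those of Gpnmb (3.68 in U17_KD and 2.40 in U17_OE), Srpx2 (3.98 and 2.25), Cfap161 (1.92 and 1.90), Tmem176b (at least 5.75-fold and 3.79-fold) and Akr1c12 (at least 6.35-fold and 2.40-fold). The shared falls chosen likewise were those of Igf2 (-3.04 and -2.12), Tmem185b (at least 4.21-fold lower in U17_KD and -1.99 in U17_OE), and Tgfbi, Acta1 and Lum, which were at least 2.43-fold, 2.79-fold and 2.87-fold lower in each clone. Tmem185b is not listed among the largest falls in U17_OE because it did not meet the rule's conditions on detection and overlap there. By probe, 127 were called oppositely and 1265 the same way, with independent lists giving 170 higher in U17_KD and lower in U17_OE, 189 the reverse, 184 higher in both and 175 lower in both; the observed counts were 66, 61, 681 and 584. Without U17_OE replicate 3 the opposite count was 207. Across probes, which are not independent replicates, the fold changes had r = 0.50, and unchanged groups simulated against the shared WT arrays gave 0.501. The covariance was 0.0741, against 0.0114 in the simulation. With the WT arrays split between the comparisons, r averaged 0.398 and the counts averaged 73.5 opposite and 612 the same way. Each comparison then had 2 WT arrays in place of 4, which adds noise and lowers the number of calls of both kinds. These lower values therefore do not measure the part due to shared WT arrays.

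**Figure D4:**
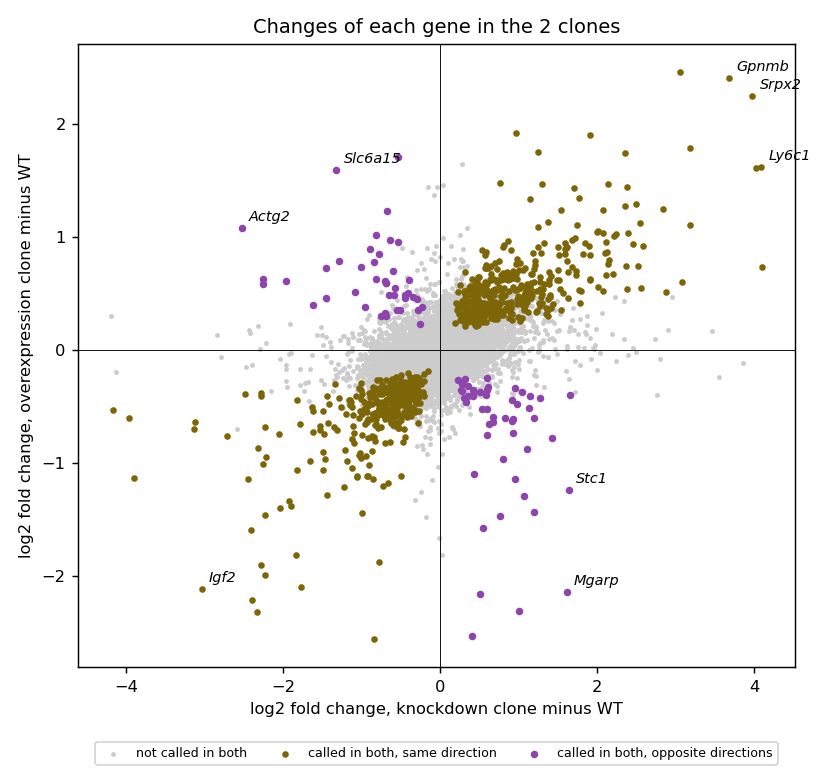
Each point is 1 of 9108 genes, with the log2 fold change of U17_KD minus WT on the horizontal axis and of U17_OE minus WT on the vertical axis. Genes called in both comparisons are brown where the directions match (414 higher and 365 lower) and purple where they oppose (50 and 42); Mgarp and Stc1 lie at the lower right and Actg2 and Slc6a15 at the upper left, at fitted values where a gene was not detected.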

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

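The tests of U17_OE replicate 3 and of matched lists for the hypoxia genes, and those of split WT arrays for the changes shared by the clones, were chosen after the results were seen; the counts over other splits of the arrays were planned before.

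Single arrays stood away from the other 3 of their group in 25 of 411 groups examined over the named genes and array measures, by the gap to the nearest array as a share of the range. Chance gives about 1 in 20 such groups, 20.6 here. U17_OE replicate 3 accounted for 6: Fbln2 (0.965), Dkk3 (0.951), Slc17a6 (0.919), Rrm2 (0.907), Rps15 (0.886) and Ndn (0.858). U17_KD replicate 3 accounted for 5, in Tspo (0.945), Rpl4 (0.934), Slc1a3 (0.92), Stc1 (0.895) and Krt14 (0.848), and U17_KD replicate 4 for 4, in Ltbp1 (0.862), Lipa (0.861), Rcc1 (0.859) and Pwp2 (0.849). WT replicate 2 stood away in Cfap161 (0.972), Rplp0 (0.9), Lpl (0.883) and Serpina3n (0.856), and WT replicate 1 in Slc17a6 (0.891) and Tmem181a (0.861). U17_OE replicate 1 did so in Gstm2 (0.893) and Lipa (0.868), U17_OE replicate 4 in Ptx3 (0.875) and U17_OE replicate 2 in Gbp2 (0.849).

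Hypoxia genes were lower in U17_OE than in WT and than in U17_KD, whereas their rise in U17_KD over WT was lost with an estimated correlation (adjusted p = 0.135) and without U17_KD replicate 3 (adjusted p = 0.0643). The array that lies apart does not carry the pattern, since without U17_OE replicate 3 the adjusted p of the list between the clones was 1.62e-08 (7.21e-09 to 0.00508 over the 21 alternatives run for lists). A shift of abundant genes between the clones is argued against by 10000 lists matched on mean level, of which none reached the list's median of 0.57 (percentile 100). What stays open is a difference in oxygen or cell density between the dishes, for which the labels hold no record, and a difference between clones unrelated to U17, since each group is 1 clone. A hypothesis that U17 level acts on these genes was not tested apart from those.

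Genes called in both clones mostly moved the same way against WT. The shared WT arrays do not account for all of it: with these arrays split between the comparisons, the lowest covariance was 0.0595, above the highest simulated covariance from shared arrays, 0.0119. U17_OE replicate 3 does not account for it, since 1885 probes were called the same way without it. Selection for a stable clone, or a property of the WT cultures, stays open, because no control clone with an empty construct is among the groups. No biological explanation was tested.

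The counts were also taken over other splits of the same arrays. Those splits mix the real groups, so where the groups differ their spread widens and few probes are called. A larger real count therefore shows only that the groups differ, and 1 of 35 is the smallest share possible. The real split of 8 arrays was the only 1 of 35 to give as many calls in each comparison: 6237 against a highest other of 0 for U17_KD and WT, 1925 against 8 for U17_OE and WT, and 5024 against 9 between the clones. Among 100 regroupings of the 12 arrays only the real 1 gave as many opposite changes (127, highest other 0) or changes the same way (1265, highest other 92). Regroupings mix the real groups as well, so this does not show an excess of opposite changes. Independent lists gave 170 probes higher in U17_KD and lower in U17_OE and 189 the reverse, above the 66 and 61 observed. For the number of gene lists called at the preset correlation, 1 of 35 splits reached the real value of 8 for U17_KD and WT (highest other 7) and 1 of 35 reached 6 for U17_OE and WT (highest other 4). Between the clones 4 of 35 splits gave 5 lists or more, the real value, with a highest other of 5, so chance was not excluded for that number. Mixed splits can keep part of the real difference between the groups, so none of these list counts is set against pure chance.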

How the results depend on the processing

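Normexp fitted to each array's own values was added after the data were seen; the other alternatives were planned. No direction of a called named gene or called list reversed, and r kept its sign. The directions of the other called probes were not compared between the alternatives. The calls in U17_OE minus WT were 1193 with 2 groups in the fit and 956 at an adjusted p under 0.01. At that threshold 3254 probes were called between the clones, 68 oppositely and 627 the same way; at least 2-fold changes were shown by 842, 152 and 587 probes in U17_KD minus WT, U17_OE minus WT and U17_KD minus U17_OE, with 8 opposite and 91 the same way. Higher thresholds call fewer probes by construction. With 2 groups in the fit U17_KD minus WT had 7535 calls against 6237, and 4546 probes were called between the clones against 5024. The SDs of differences from group mates were 0.182 to 0.203 in U17_KD and 0.231 to 0.393 in U17_OE. A variance shared by the 3 groups can therefore add calls in U17_OE minus WT and cost calls in U17_KD minus WT, which was not tested further. These 2-fold counts depend on the background setting, which was itself chosen after a preliminary fit. They were 572, 91 and 385 with normexp fitted to each array and 539, 84 and 350 with an offset of 50, which shrinks the folds of dim probes. Without the normexp correction and with quantile normalization run again they were higher, at 943, 186 and 661. With an estimated correlation between genes, 1, 2 and 3 lists were called in place of 8, 6 and 5. The estimate exceeded the preset 0.01 for the cholesterol synthesis (0.0946) and extracellular matrix (0.0630) lists. It lay below 0.01 for the interferon (-0.0206), cell cycle (-0.00700) and snoRNP lists (3.65e-05). Their camera p in U17_KD minus WT rose all the same, for the cell cycle from 0.00523 to 0.0111. A larger correlation therefore does not account for every lost call.

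Leaving out 1 array at a time gave 5420 to 7386 calls in U17_KD minus WT, 1261 (without U17_OE replicate 4) to 2981 (without U17_OE replicate 3) in U17_OE minus WT and 4116 to 5795 between the clones. Opposite calls ranged from 95 to 207, calls the same way from 857 to 1885, and r from 0.465 to 0.511. Of 248 calls of named genes, 239 to 247 were kept, and the lists called numbered 6 to 9, 5 to 6 and 5 in the 3 comparisons. The named genes kept their side of the threshold in 5379 cases, were lost in 89 and gained in 1, and the lists, over their 21 alternatives, in 1292, 24 and 7. Fits of only the compared groups, without a variance trend or with array weights were not run for lists. The same replicate number did not mark paired samples: 0 same-numbered pairs had deviations correlated over 0.1, 0 of 8 samples in each comparison correlated best with its own number, and with the replicate block 5659, 1398 and 4397 probes were called. The lowest same-numbered correlation was -0.382, in U17_OE and WT. Whether arrays with different numbers share a batch was not tested. On principal component 3 (11.9% of the variance), WT replicate 2 (18.7) and U17_OE replicate 3 (28.9) were each highest in their group. Neqc on the unnormalized signals of the clone arrays and a slide block were not run, since those columns name no sample and no slide. Signal near background limits dim probes: a probe detected on no array of a group has only a bound there, and differences of probes detected on some of its arrays rest partly on values below the detection level.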

Other observations

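The tests of imprinted genes were chosen after the results were seen. The test of lysosomal genes was written before its result, although Ctsk and a few other members had been seen. Those members stayed in the lysosomal list, so its p-values rest partly on values already known. The list was not tested without them.

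Lysosomal genes rose in the knockdown clone. Of 44 measured members of a list of 56 lysosomal hydrolases, membrane proteins and proton pump subunits, written after Gpnmb was seen to lead both clones, 22 were higher and 4 lower than in WT (23 and 4 adjusted over the list alone). Arsa, arylsulfatase A, rose by 1.04, Gla, alpha-galactosidase, by 0.79, Ctsa, cathepsin A, by 0.78 and the proton pump subunit Atp6v0d1 by 0.68, while Ctsl, cathepsin L, fell by 0.76. The camera p of the list was 0.000148 at the preset correlation and 0.00141 with an estimated correlation, and it ranged from 7.46e-05 to 0.000297 with 1 array left out. In U17_OE 4 members were higher and 5 lower (4 and 5 adjusted over the list alone), with a median of -0.00471 and a camera p of 0.844. A median at or below 0 had been set beforehand as evidence against a general rise, and by that rule the values argue against one in U17_OE. The median lay at percentile 53.8 of lists matched on mean level. That it must lie below 0 by more than its spread was added after this result was seen, and only on that stricter reading does U17_OE stay undecided. A general rise of lysosomal genes may therefore accompany the rise of Gpnmb in U17_KD, and no such shift was found in U17_OE, where Gpnmb rose too.

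Imprinted genes stood among the largest changes: Igf2 fell in both clones, Snurf was not detected in U17_KD, and Ndn fell in U17_OE. Against a probe that misreads its gene, the 2 other probes of Snurf (100% of them) were also called lower and detected on 0 U17_KD arrays, with bounds of at least 8.91-fold and, for a probe dim in WT, 1.25-fold. A candidate explanation is that clones differ epigenetically at imprinted loci. Over all 27 measured members of a list of 61 imprinted genes, the share changed at least 2-fold lay at the 98.1th percentile of 10000 lists matched on mean level in U17_OE and at 86.7 in U17_KD, but the list was written because of these genes, so this decides nothing. Over the 24 members left without Igf2, Ndn and Snurf, 1 changed 2-fold in U17_KD (percentile 32.2, share 4.17% against a matched mean of 4.60%) and 0 in U17_OE, where a percentile of 0 is the lowest possible and the matched mean of 0.788% is under 1 gene, so the test decides nothing there and the hypothesis stays open; 12 of the 24 were called in U17_KD (40.5% of all genes were) and 4 in U17_OE (12.8% of all genes).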
